A study of Mus musculus with 2 samples.

How the data were processed

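Total RNA was extracted from sorted mouse type II pneumocytes at postnatal days 7 and 28, reverse transcribed, made into libraries with a tagmentation kit (Nextera XT) and sequenced as paired Illumina reads, per the labels' protocols. The submitters' processing notes name TopHat, TopHat2 2.0.9 and the mouse build GRCm38 (mm10), with no role or order given. Expression values were deposited by the authors as RPKM, reads per kilobase of gene scaled to library depth, with 1 column per sample, per the file headers. The program that computed the RPKM values, the gene annotation, the filters and the sort markers are not given in the sources used here. Both columns matched the title of 1 sample each, and 0 columns of per-sample values were left unused. RPKM fixes no common total, so a few abundant genes can change the share left for all others.

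The table had 24369 rows. In it, 27 rows carried names that a spreadsheet had turned into dates, and were kept under those names. A further 53 rows held the same pair of values as another row. Symbols were matched, older names included, to the supplied GRCm38 annotation for positions and transcript lengths. Reads of near-identical genes (globins, Lyz1 and Lyz2, chitinase-like genes, H2 genes, Hspa1a and Hspa1b) may have been split or shared by the counting, and nothing states that the counting used strand.

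Depth was recovered from the RPKM values themselves. For genes with a single transcript length, low RPKM values multiplied by length fell on whole steps within 0.05 for 59.8% of 2481 low genes at P7 and 58.4% of 2278 at P28, where chance gives 10%. The step gives 0.0568 RPKM at P7 and 0.0407 at P28 for 1 read on 1 kilobase, and so about 17600000 and 24600000 reads in the denominators, a ratio of 1.40. Independently of length, the commonest low ratio between the libraries was 0.716, in 242 of 1062 genes. Read numbers per gene, exact (Clopper-Pearson) 95% intervals of the ratio of RPKM values, and floors of 3 reads come from these steps. Of 23664 genes with a transcript length, 17938 had a single one. The others took the mean of their lengths, so their read numbers, interval widths and floors are approximate. Read numbers, intervals and floors assume that the smallest step is 1 read. PCR reads without molecular identifiers are not independent molecules, so intervals and floors cover counting error only.

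With 1 library per age there was no test. The log2 ratio of (RPKM + 1) at P28 over (RPKM + 1) at P7 was taken for genes with 1 RPKM or more in at least 1 library. The pseudocount of 1 understates the difference of low genes, and folds printed with intervals are plain ratios of RPKM, so a plain ratio can exceed 2 in a gene within 2-fold on the log2 scale. A gene was called higher or lower at 2-fold. For 38 gene lists, the median log2 ratio was placed among those of 10000 random lists of the same size matched on mean expression in 20 bins. A list stood apart under percentile 2.5 or over 97.5, as a description of these libraries, and 32 lists had the 5 measured genes needed. Of these, 26 stood apart, 15 above and 11 below.

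Lists, design and the rule for named genes were fixed before the data were examined. The rule took 16 genes always named (such as Sftpc, Mki67 and Igf2), the 12 genes with the highest and the 12 with the lowest log2 ratio among genes of 10 RPKM or more in at least 1 library, without Gm-numbered, Rik and similar names, and in each list up to 4 genes of 5 RPKM or more with the largest absolute ratio, 130 genes in all. Named after their values were seen were Rnase4, Etv5, Cdipt, Lipa, Cyp2f2, Hp, Cyp2a5, Scgb3a2, Aldh1a7, Cbr2, Foxj1, Dynlrb2, Rsph1, Ccdc153, Tppp3, Sec14l3, Tekt1, Lrg1, Mcm2, Gins2, Rrm2, Uhrf1, Cdkn2b, Spock2, Ager, Hopx, Pdpn, Aqp5, Sox9, Foxp2, Emcn, Pecam1, Sparc, Inmt, Pdgfra, Dcn, Postn, Lox, Aplnr, Ptprc, Cd68, Marco, C1qa, Srgn, Cd79b, Acta2, Hspb1, Gstm1, Cyp4b1, Zbtb16, Gapdh, Hprt, Actb, Rn45s, Lars2, Malat1, Ddx3y, Kdm5d and Uty. Values of a few single list members are not reported here.

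The procedure was tested on simulated data for this comparison. Over 20 pairs drawn from unchanged expression of 23664 genes at the recovered depths, 0 to 3 genes were called 2-fold apart. All 50 genes changed 3-fold and all 50 changed 4-fold were called (100%), as were 98% of 50 genes lowered 3-fold and 0% of 50 changed 1.5-fold. The changed genes were drawn from those with a mean of 5 RPKM or more, so recovery of lower genes was not tested. Of 400 unshifted lists of 25 genes 4.75% stood apart, and of lists shifted by 0.3 or -0.3, drawn from 9653 genes, 99% and 97% did. The log2 ratios were shuffled among genes for this, so a low rate for unshifted lists was set in advance. It does not give the rate for lists whose genes vary together.

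Alternatives changed the pseudocount to 0.1 or 5, the filter (none, or 5 RPKM), the scaling (the same total, median log2 ratio set to 0, upper quartile), the genes used, the number of bins, the matching, and the list median to the mean. Removing a trend with transcript length and GC content, leaving out Rn45s, Lars2 and Malat1, and restricting to genes whose counting interval excludes 1 were added after seeing the data. Computation used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.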

Results

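The data describe alveolar type 2 cells (type II pneumocytes), the cells that make and recycle pulmonary surfactant, sorted from lungs of wild-type C57BL6 mice. There were 2 libraries, 1 from postnatal day 7 (P7) and 1 from postnatal day 28 (P28), and each gave 1 RPKM value (reads per kilobase of gene, scaled to the depth of the library) for 24369 gene rows. The spacing of the lowest values put the reads behind the RPKM denominator at about 17600000 for P7 and 24600000 for P28. Over the 23664 genes with a known transcript length, this gave about 4520000 and 6960000 reads. Rows without a length, such as the abundant ribosomal precursor RNA Rn45s, are not in these 2 sums. With 1 library per age, no difference below has a replicate check, no p-value can be given, and "higher" or "lower" compares these 2 libraries. Each interval is a 95% exact counting interval of the RPKM ratio, which covers counting error only.

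The comparison asks how the transcripts of type 2 cells differ between the first postnatal week and the age of 28 days. Lists of airway genes, of surfactant and type 2 identity genes, and of cholesterol synthesis genes stood higher at P28 relative to other genes. Abundant genes of the first 2 lists that were at least 2-fold higher included Lyz2 (lysozyme, 3.55-fold, interval 3.51 to 3.59) and Scd1 (stearoyl-CoA desaturase, 3.68-fold, 3.62 to 3.73). Another was the club cell secretory protein gene Scgb1a1 (2.68-fold, 2.65 to 2.70). Of the surfactant protein genes, Sftpa1 was 2.35-fold higher as deposited, while Sftpc (1.81), Sftpd (1.85) and Sftpb (1.45) had ratios under 2. Lists of proliferation, imprinted growth, endothelial, fibroblast and erythroid genes stood lower at P28. Mki67, the proliferation marker, was 4.14-fold lower (3.84 to 4.48), and Mest, an imprinted gene, was 22-fold lower (13.7 to 40.1). Xist was lower and Y-linked genes were higher at P28. Libraries from animals of opposite sex would give this pattern, so age and sex cannot be told apart in any difference here.

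Of 9653 genes with an RPKM of 1 or more in at least 1 library, 114 were at least 2-fold higher at P28 and 189 at least 2-fold lower, on the scale of log2(RPKM + 1). The other 9350 genes (96.9%) lay within 2-fold. Across genes, which are not independent replicates, the libraries had a Pearson r of 0.946 and a Spearman rho of 0.916. Of the 303 genes at least 2-fold apart, 299 had a transcript length, and for 296 of these the counting interval of the ratio excluded 1. The total RPKM was 108758 at P7 and 143071 at P28, and the 10 most abundant genes held 27.9% and 44.0% of it, with 9 of them shared. When each library was rescaled to the same total, the split became 65 higher and 445 lower, so that 12.7% rather than 37.6% of the genes apart were higher. That rescaling moved the median log2 ratio of all genes by -0.29, from -0.08 to -0.38. Pseudocounts of 0.1 and 5 in place of 1 gave 226 higher and 530 lower, and 39 higher and 34 lower. List directions are given relative to the other genes, through random lists matched on expression, and every list median above 0 and up to 0.32 turned negative as a raw value on the rescaled scale.

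**Figure D1:**
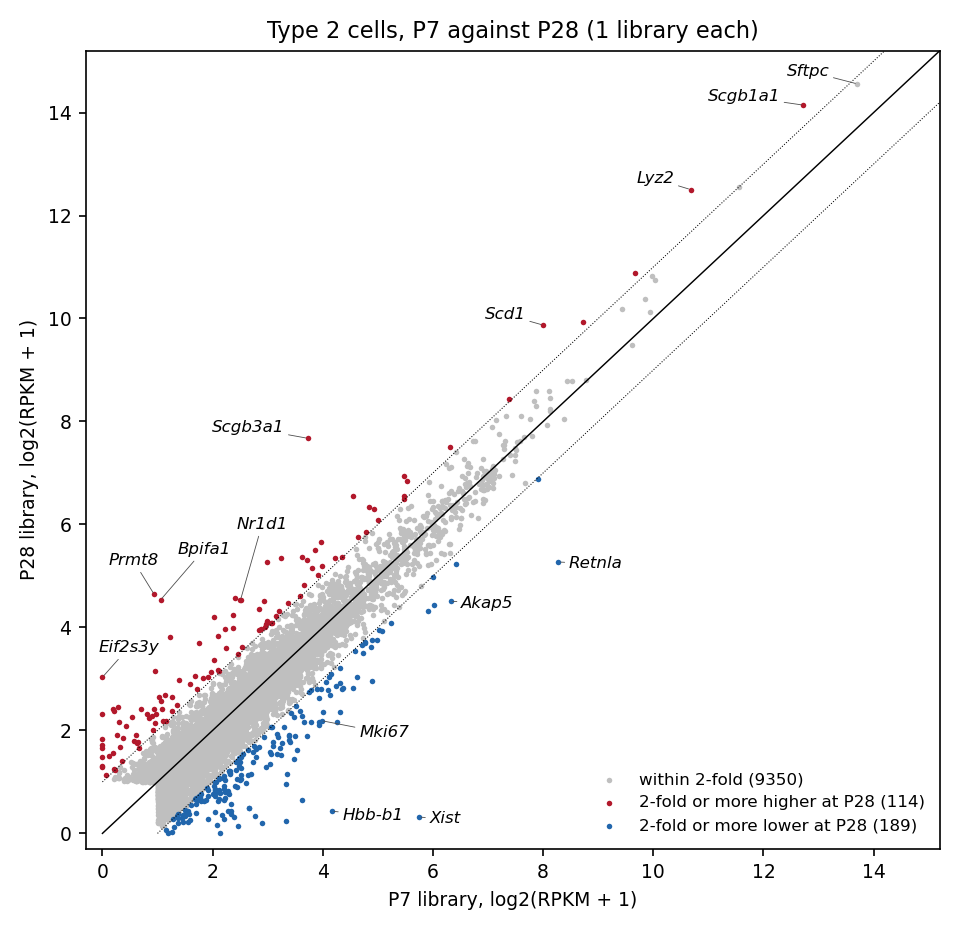
Each dot is 1 of 9653 genes, with log2(RPKM + 1) of the P7 library on the x axis and of the P28 library on the y axis. The solid line marks equal values and the dotted lines 2-fold, with 114 genes (red) above and 189 (blue) below them. Scgb3a1 and Bpifa1 lie far above the lines, and Xist and Retnla far below.

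Outside the Gm-numbered and Rik genes, the 12 genes with the largest log2 ratio among those reaching 10 RPKM were Scgb3a1, Prmt8, Bpifa1, Nrn1, Rgcc, Hsph1, Aox3, Glul, Itih4, Nr1d1, Pon1 and Scd1. Prmt8, an arginine methyltransferase, went from 0.918 RPKM at P7 to 24.0 at P28, a ratio of 26.1 (19.4 to 36.1). Nrn1 (neuritin) was 9.76-fold higher (7.00 to 13.9) and Rgcc, a regulator of the cell cycle, 5.44-fold higher (4.48 to 6.72). Itih4 was 4.78-fold higher (4.20 to 5.49), and Pon1, a paraoxonase, 5.04-fold higher (3.86 to 6.67). The 12 genes with the smallest log2 ratio were Xist, Hbb-b1, Retnla, Chil4, Aqp1, Rian, Ctgf, Id3, Fbln5, Ano1, Scn7a and Akap5. Chil4, a chitinase-like gene with close paralogs that can share its reads, was 20-fold lower at P28 (13.1 to 33.5). Fbln5, an elastic fibre gene, was 5.12-fold lower (4.49 to 5.83) and the sodium channel gene Scn7a 4.44-fold lower (4.01 to 4.93).

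Genes of surfactant and type 2 identity included the most abundant gene of both libraries, and 5 of 29 were at least 2-fold higher at P28, none lower. With equal totals 2 remained higher, Lyz2 and Scd1, and 1 was lower, Cldn18, while Sftpa1, Elovl1 and Rnase4 went from log2 ratios of 1.23, 1.31 and 1.19 to 0.84, 0.92 and 0.80. Sftpc (chromosome 14, 70520949 to 70524081 in GRCm38, minus strand, protein coding) led both libraries, at 13343 RPKM or 12.3% of the total at P7 and 24085 RPKM or 16.8% at P28, a ratio of 1.81 (1.80 to 1.81). Sftpa1 was 2.35-fold higher (2.32 to 2.38), and Lyz2 went from 1635 to 5809 RPKM. The remaining genes at least 2-fold higher were Scd1 (255 to 936 RPKM), Elovl1, a fatty acid elongase (45.4 to 114 RPKM), and Rnase4 (78.3 to 180 RPKM). Sftpb had a ratio of 1.45 (1.42 to 1.47), Sftpd 1.85 (1.78 to 1.93) and Lamp3, a lamellar body membrane gene, 1.47 (1.44 to 1.5). The lipid transporter gene Abca3 had 61.7 and 65.1 RPKM, a log2 ratio of 0.08 that became -0.31 after rescaling to the same total. Lyz1, a near copy of Lyz2 whose reads can be confused with it, had 785 and 716 RPKM, the lineage factor gene Nkx2-1 60.1 and 47.5, and Etv5 85.3 in both libraries. The list median was 0.29, at percentile 99.8 of 10000 random lists. Genes of airway cells, which can also express some of this list, stood higher as a list in the same library. Macrophages also make Lyz2. The 8 of 24 macrophage markers measured stood higher as a list, but not without the filter or by the mean. The macrophage genes Marco and C1qa had no read in either library, and Ptprc, a pan-leukocyte gene, had 8 reads and 1.

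Cholesterol synthesis genes stood higher at P28 relative to other genes, and fatty acid genes did so under some settings only. In cholesterol synthesis, 2 of 25 genes were at least 2-fold higher and none lower, namely Pmvk (phosphomevalonate kinase, 3.98-fold, 3.10 to 5.20) and Idi1 (isopentenyl-diphosphate isomerase, 2.26-fold, 2.03 to 2.53). Msmo1 and Nsdhl, which act later in the pathway, had ratios of 1.87 (1.58 to 2.22) and 1.80 (1.52 to 2.14), and the list median of 0.26 was at percentile 100. With equal totals only Pmvk of this list was 2-fold higher, and Idi1 went from a log2 ratio of 1.08 to 0.72. In fatty acid and phospholipid synthesis, 3 of 32 genes were higher, namely Scd1, Elovl1 and Lpin2, a phosphatidate phosphatase (2.68-fold, 2.5 to 2.86), while Fasn, fatty acid synthase, had 31.5 and 51.8 RPKM. That list, with a median of 0.11 at percentile 96.7, did not stand apart from random lists, but did in 5 settings, such as among genes of 5 RPKM or more or by the mean. With equal totals Scd1 alone was higher in it and Cdipt was lower, and Lpin2 had a log2 ratio of 0.98. Of 36 lysosome and lamellar body genes, Prdx6 was higher (2.22-fold, 2.03 to 2.43) and Lipa, the lysosomal acid lipase gene, was lower, from 3.63 to 0.89 RPKM. The list median was 0.07 at percentile 90.7, within the range of random lists except without expression matching, Prdx6 lost its 2-fold call with equal totals (log2 ratio 0.73), and Npc2, a cholesterol carrier of the lysosome, had 98.9 and 145 RPKM.

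Genes of airway cells stood higher at P28 as a list. Scgb1a1 (chromosome 19, 9083636 to 9087958, minus strand, protein coding) went from 6764 RPKM or 6.22% of the total to 18104 RPKM or 12.7%. Scgb3a1, a secretoglobin, went from 12.2 to 203 RPKM, a ratio of 16.6 (13.9 to 20.3). Muc5b, a gel-forming mucin, was 4.03-fold higher (3.74 to 4.33) and Reg3g, an antibacterial lectin, 3.32-fold higher (2.83 to 3.92), and Cyp2f2, Hp and Cyp2a5 were also at least 2-fold higher. Scgb3a2 had 277 and 302 RPKM, a log2 ratio of 0.12 that became -0.27 after rescaling to the same total, and Aldh1a7 had 33.8 and 31.8. Of 8 ciliated cell genes, 4 had counting intervals wholly above 1, namely Foxj1 (ratio 1.36, 1.16 to 1.59), Dynlrb2 (1.51, 1.26 to 1.81), Rsph1 (1.45, 1.18 to 1.78) and Ccdc153 (1.36, 1.09 to 1.71). For 3 they lay wholly below 1, namely Tppp3 (0.861, 0.793 to 0.935), Sec14l3 (0.878, 0.847 to 0.910) and Tekt1 (0.530, 0.372 to 0.741). In all, 7 of 18 airway genes were higher and none lower, with a median of 0.52 at percentile 100. With equal totals 5 were higher, and Cyp2f2 (0.65) and Hp (0.98) fell short on the log2 scale. Of 15 basal and neuroendocrine markers 0 reached 1 RPKM, so that list was not placed.

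Genes of innate defence stood higher at P28 as a list. Of 28 genes, 6 were at least 2-fold higher, 1 was lower and 21 lay within 2-fold, with a median of 0.48 at percentile 100. With equal totals 5 were higher and 2 lower, with Sftpa1 no longer higher. Bpifa1, a secreted airway defence protein, went from 1.08 to 22.2 RPKM (20.6-fold, 13.4 to 33.5), and Lyz2, Sftpa1, Reg3g and Lrg1 (6.21 to 19.5 RPKM) were also among those higher. Reg3g is also on the airway list, and Lyz2, Lyz1, Sftpa1 and Sftpd, among others, are also on the surfactant and type 2 list. Both of those lists stood higher in the same library, so the innate defence list is not independent of them. Retnla, a resistin-like secreted protein, was the lower gene, with 309 RPKM at P7 and 37.6 at P28 (8.22-fold lower, 7.51 to 9.01). Of 16 genes of MHC class I presentation none was 2-fold apart, and the list median was 0.21 at percentile 99.2. The light chain gene B2m had 79.4 and 137 RPKM and H2-K1 46.2 and 67.6, although reads of H2 genes can be shared between paralogs. Of 9 MHC class II genes none was 2-fold apart. H2-Aa had 147 and 215 RPKM, and the invariant chain gene Cd74 had 368 and 438, a log2 ratio of 0.25 that became -0.15 with equal totals. The class II median of 0.25, at percentile 97.1, did not stand apart, but did in 5 settings, such as without expression matching. Interferon-stimulated genes had 0 of 19 genes 2-fold apart and a median of 0.07 at percentile 98.3 with a mean of -0.03, and they no longer stood apart after rescaling to the same total, without the filter, without expression matching, or by the mean.

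Proliferation genes stood lower at P28 as lists, although most lay within 2-fold. None of 34 genes of G2 and mitosis and none of 29 genes of S phase had a log2 ratio above 0. In G2 and mitosis 7 genes were at least 2-fold lower (14 with equal totals), with a median of -0.76 at percentile 0. Mki67 had 14.8 RPKM at P7 and 3.56 at P28, Top2a (topoisomerase II alpha) was 3.50-fold lower (3.09 to 3.98), Ccna2 (cyclin A2) 3.30-fold lower (2.68 to 4.07) and Ube2c 2.32-fold lower (1.90 to 2.84). In S phase and DNA replication 4 genes were lower (12 with equal totals), with a median of -0.67 at percentile 0. These were Mcm2 (2.36 to 0.663 RPKM), Gins2 (3.63 to 0.818), Rrm2 (4.71 to 1.08) and Uhrf1 (1.6 to 0.301), and the replication clamp gene Pcna had 27.5 and 19.4 RPKM. Of 18 cell cycle inhibitors and p53 targets, Cdkn1c (3.81-fold lower, 3.04 to 4.86) and Cdkn2b (4.61 to 1.63 RPKM) were lower and none was higher. That list had a median of 0.15 at percentile 99.6 and a mean of -0.02, and did not stand apart by the mean or among genes of 5 RPKM or more. Markers of endothelial cells and fibroblasts also stood lower at P28 as lists, with medians of -0.94 and -0.65.

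Imprinted and postnatal growth genes stood lower at P28 as a list, with 8 of 17 genes at least 2-fold lower, none higher, and a median of -0.76 at percentile 0. Meg3, a maternally expressed noncoding RNA, was 7.56-fold lower (6.45 to 8.90), Peg3 5.21-fold lower (4.47 to 6.09) and Igf2, insulin-like growth factor 2, 4.6-fold lower (3.21 to 6.79). Rian went from 10.2 to 1.70 RPKM. H19, below 1 RPKM in both libraries, had 0.477 RPKM at P7 and no read at P28. Against a floor of 3 reads it was 8.95-fold lower, with a lower counting bound of 6.52. Among 12 fetal RNA-binding and chromatin genes none was 2-fold apart, although the median was -0.74 at percentile 0 and 6 were lower with equal totals. Tmsb10 had 9.51 and 5.04 RPKM, Tuba1a 52.8 and 35.8, and Stmn1 34 and 35.3, a log2 ratio of 0.06 that became -0.33 with equal totals. These lists also hold genes of fibroblasts and other cells, and the fibroblast and endothelial lists stood lower in the same library.

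Type 1 cell genes were lower at P28 as a list, with 5 of 24 lower (15 with equal totals), 1 higher and a median of -0.75 at percentile 0. Akap5, a kinase-anchoring protein, went from 78.9 to 21.7 RPKM (3.63-fold lower, 3.49 to 3.77), and Igfbp2 was 3.67-fold lower (3.08 to 4.42), Sema3a 3.69-fold lower (3.30 to 4.13) and Scnn1g 2.47-fold lower (2.28 to 2.68), with Spock2 at 26.2 and 12 RPKM. The gene that was higher was Cyp2b10 (3.27-fold, 2.83 to 3.80). Other type 1 genes lay within 2-fold, with 119 and 89.1 RPKM for Ager, 40.3 and 30.6 for Hopx, and 11.0 and 5.70 for Pdpn, which was lower with equal totals (log2 ratio -1.19). Aqp5 had 18.5 and 19 RPKM, a log2 ratio of 0.04 that became -0.33 with equal totals. Epithelial junction and keratin genes had 0 of 25 genes 2-fold apart, but a median of -0.32 at percentile 0.03, and 4 were lower with equal totals. These included Cldn18, a tight junction gene, with 202 and 111 RPKM, Krt7 with 17.5 and 8.43, and Tjp1 with 25.9 and 14.9. Endothelial and fibroblast markers, whose cells can also express some of these genes, stood lower as lists in the same library.

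Regulators of lung development held genes that were lower at P28 and none at least 2-fold higher. Of 40 lung epithelial transcription factors, 5 were lower (8 with equal totals) and none was higher, but the median of -0.13, at percentile 10.9, stood apart from random lists only by the mean or among genes of 5 RPKM or more. Among those lower were Id2 (2.06-fold, 1.90 to 2.24), Elf5 (2.18-fold, 1.90 to 2.5), Sox9, a factor of distal lung progenitors (4.25 to 0.255 RPKM) and Foxp2 (4.84 to 1.91 RPKM). Among targets and components of FGF, WNT, BMP, Notch and Hippo signalling, 6 of 29 genes were lower (9 with equal totals) and none was higher, with a median of -0.33 at percentile 0.03. Ctgf, a Hippo pathway target, was 4.53-fold lower (3.92 to 5.24), Id3 4.20-fold lower (3.58 to 4.91), Id1 3.68-fold lower (2.89 to 4.72) and the ligand gene Shh 3.37-fold lower (2.79 to 4.09). Endothelial and fibroblast markers, whose cells can also express genes of these pathways, stood lower as lists in the same library.

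Endothelial, fibroblast and erythroid genes stood lower at P28 as lists. Of 17 endothelial genes 8 were lower (11 with equal totals), none was higher, and the median was -0.94 at percentile 0. Cdh5 (VE-cadherin) was 3.40-fold lower (2.95 to 3.92), Calcrl 2.18-fold lower (1.98 to 2.41), Emcn 4.86-fold lower (3.38 to 7.35) and Pecam1 2.60-fold lower (2.11 to 3.20). Esam had 9.68 and 10.2 RPKM, a log2 ratio of 0.07 that became -0.29 with equal totals. Of 20 fibroblast and matrix genes 6 were lower (9 with equal totals) and 2 higher, with a median of -0.65 at percentile 0. The most abundant, Sparc, a matrix glycoprotein gene, had 240 RPKM at P7 and 117 at P28. Vim was 3.95-fold lower (3.23 to 4.87), Gpc3 3.02-fold lower (2.63 to 3.47), Eln (elastin) 2.70-fold lower (2.37 to 3.07), and Col1a1 had 2.78 and 1.19 RPKM. The higher genes were Mgp (matrix Gla protein, 4.28-fold, 3.14 to 6.05) and Inmt, which had no read at P7 and 2.31 RPKM at P28. Against a floor of 3 reads Inmt was 14.6-fold higher, with a lower counting bound of 11.5. Of 7 erythroid genes 6 were lower, all globins with near-identical copies, and the median was -2.31 at percentile 0. Hbb-b1 and Hbb-bs were both 48.8-fold lower and may hold the same reads, so these genes are not independent members of the list. Hbb-b1 had 17 RPKM at P7 and 0.348 at P28, and Hba-a1 6.4 and 0.149.

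Leukocyte genes differed widely in level. The pan-leukocyte gene Ptprc had 0.0902 and 0.00718 RPKM, which is 8 reads and 1 read, and the macrophage genes Marco and C1qa had none in either library. Of 24 macrophage markers, 8 reached 1 RPKM and none was 2-fold apart. Their median was 0.25 at percentile 99.2, with ratios of 2.36 for Cd68 (1.14 to 5.38) and 1.36 for Plet1 (1.15 to 1.61). The most abundant was Cd9 (37.0 and 43.2 RPKM, a log2 ratio of 0.22 that became -0.17 with equal totals). Too few genes were measured to place 4 further lists. Of 4 pan-leukocyte genes, Srgn was lower (4.36 to 1.34 RPKM), and Lcp1 had 15.7 and 20.7 RPKM. Ly6c2, the 1 measured granulocyte or monocyte gene, had 4.80 and 7.35 RPKM, and Cd79b, the 1 measured lymphocyte gene, 2.84 and 3.02. Of 4 smooth muscle and pericyte genes 3 were lower, among them Acta2 (2.03 to 0.458 RPKM). The 5 mesothelial genes had a median of 0.45 at percentile 99.9 but a mean of -0.05, with Msln 4.39-fold lower (3.27 to 5.91). The macrophage and mesothelial lists did not stand apart without the filter or by the mean.

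**Figure D2:**
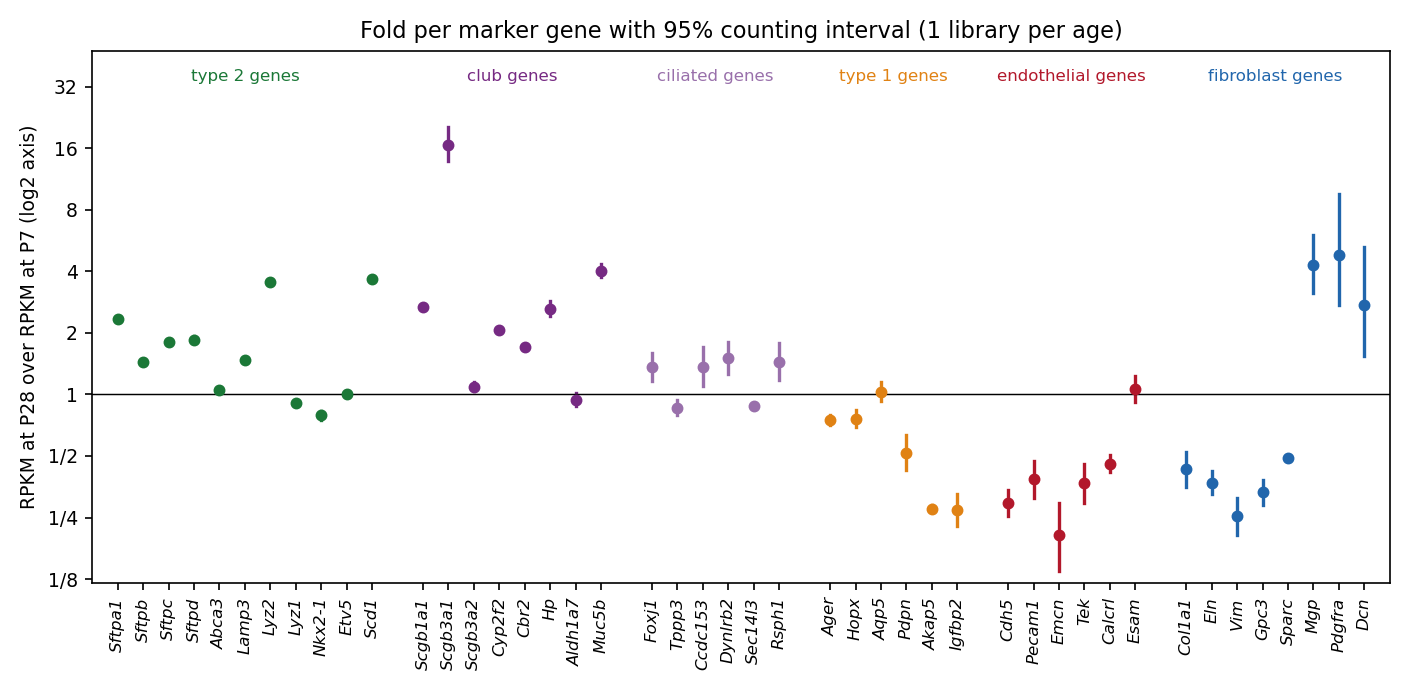
Points give the P28 RPKM over the P7 RPKM on a log2 axis for marker genes of 6 kinds, and bars the 95% counting interval, with 1 library per age. Scgb3a1 stands at 16.6 while Scgb3a2 stands at 1.09, Cdh5 and Emcn lie below 1, Esam lies at 1.06, and Mgp, Pdgfra and Dcn lie above the other fibroblast genes shown.

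Stress and detoxification genes stood higher at P28 as lists. Of 27 genes of heat shock and the unfolded protein response, 7 were higher and none was lower, with a median of 0.61 at percentile 100. With equal totals 4 were higher, and Herpud1 (0.79), Dnaja1 (0.75) and Hspb1 (0.71) fell short on the log2 scale. Hsph1, a large heat shock chaperone, was 5.67-fold higher (4.88 to 6.63), Dnajb1 3.19-fold (2.92 to 3.48), Herpud1 2.34-fold (2.09 to 2.62) and Dnaja1 2.25-fold (2.12 to 2.39). Like the immediate-early list below, the heat shock list was fixed as a check on sample quality. An effect of cell handling on it was not tested and cannot be told apart from age. Of 36 NRF2 and xenobiotic genes 8 were higher and none was lower, with a median of 0.53 at percentile 100. With equal totals 5 were higher, and Prdx6, Gstm1 and Cyp4b1 fell short. Aox3 (aldehyde oxidase) was 5.26-fold higher (4.70 to 5.89), Fmo2 (a flavin monooxygenase) 3.08-fold (2.65 to 3.58), and Cyp2b10 and Prdx6 belong to this list too. Several of these enzymes are also made by club cells, and airway genes stood higher as a list in the same library. Of 27 immediate-early genes, which dissociation can induce, 1 was higher, Zfp36 (2.81-fold, 2.68 to 2.94), and the median was 0.16 at percentile 99.6, which did not stand apart among genes of 5 RPKM or more.

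Glucocorticoid-induced and clock genes included both higher and lower ones. Of 17 glucocorticoid-induced genes 4 were higher and 1 was lower, with a median of 0.32 at percentile 100, and with equal totals 3 were higher and 2 lower, without Klf9 (log2 ratio 0.68). Glul (glutamine synthetase) was 4.71-fold higher (4.25 to 5.23), Sult1a1 2.98-fold (2.36 to 3.79) and Klf9 2.26-fold (2.01 to 2.56), Zbtb16 had 0.222 and 4.52 RPKM, and the metallothionein gene Mt2 was 3.22-fold lower (2.46 to 4.31). Of 14 circadian clock genes 1 was higher and 2 were lower. Nr1d1 (a transcriptional repressor of the clock) was 4.73-fold higher (4.12 to 5.48), and Per3 was 2.33-fold lower (2.08 to 2.62). Their median of 0.04, with a mean of -0.02, was at percentile 90.7 and did not stand apart. Of 25 sodium and fluid transport genes, Kcnj15, a potassium channel gene, was higher (2.16-fold, 2.06 to 2.26), a call lost with equal totals (log2 ratio 0.70). Lower were Aqp1, a water channel gene (5.18-fold, 4.47 to 6.02), Ano1, a chloride channel gene (4.35-fold, 3.87 to 4.91), and Scnn1g, an epithelial sodium channel subunit. That list had a median of 0.04 at percentile 79.6, a mean of -0.12, and did not stand apart.

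Oxidative phosphorylation and ribosomal protein genes held no gene 2-fold apart. The 46 nuclear genes of oxidative phosphorylation had a median of 0.15 at percentile 98.6 that did not stand apart by the mean or with the length and GC trend removed. Examples were Cox7a2 (16.4 and 25.6 RPKM) and Ndufb5 (12 and 18.8 RPKM). The 57 cytosolic ribosomal protein genes had a median of -0.12 at percentile 0.1 that did not stand apart without expression matching, with Rpl4 at 123 and 88.4 RPKM and Rps28 at 62.9 and 86.4. Gapdh had 120 and 100.3 RPKM, Hprt 10.48 and 10.40, and Actb 278 and 295, a log2 ratio of 0.09 that became -0.31 with equal totals. The 15 mitochondrial genome transcripts were not analysed here. Ribosomal precursor RNA (Rn45s) had 2995 and 5978 RPKM, and the noncoding RNA Malat1 had 1052 and 1711. Lars2, a gene whose reads can include ribosomal-like repeats, was higher at P28, with 424 and 981 RPKM, a call lost with equal totals (log2 ratio 0.81).

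Sex-linked genes separated the libraries. Xist, the noncoding RNA of the inactive X chromosome (chromosome X, 103460366 to 103483254, minus strand), had 52.7 RPKM at P7 and 0.245 at P28, a ratio of 215 in favour of P7 (178 to 263). The Y-linked genes Eif2s3y, Ddx3y, Uty and Kdm5d had no read at P7 and 7.19, 4.01, 2.57 and 2.16 RPKM at P28. Against a floor of 3 reads at P7 they were 77.5-fold, 108-fold, 71.1-fold and 101-fold higher, with lower counting bounds of 62.5, 87.8, 57.5 and 81.8. With 4 of 5 measured genes higher and 1 lower, the list median was 1.83 at percentile 100. Libraries from animals of opposite sex would give this pattern, so sex and age cannot be told apart between these 2 libraries.

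**Figure D3:**
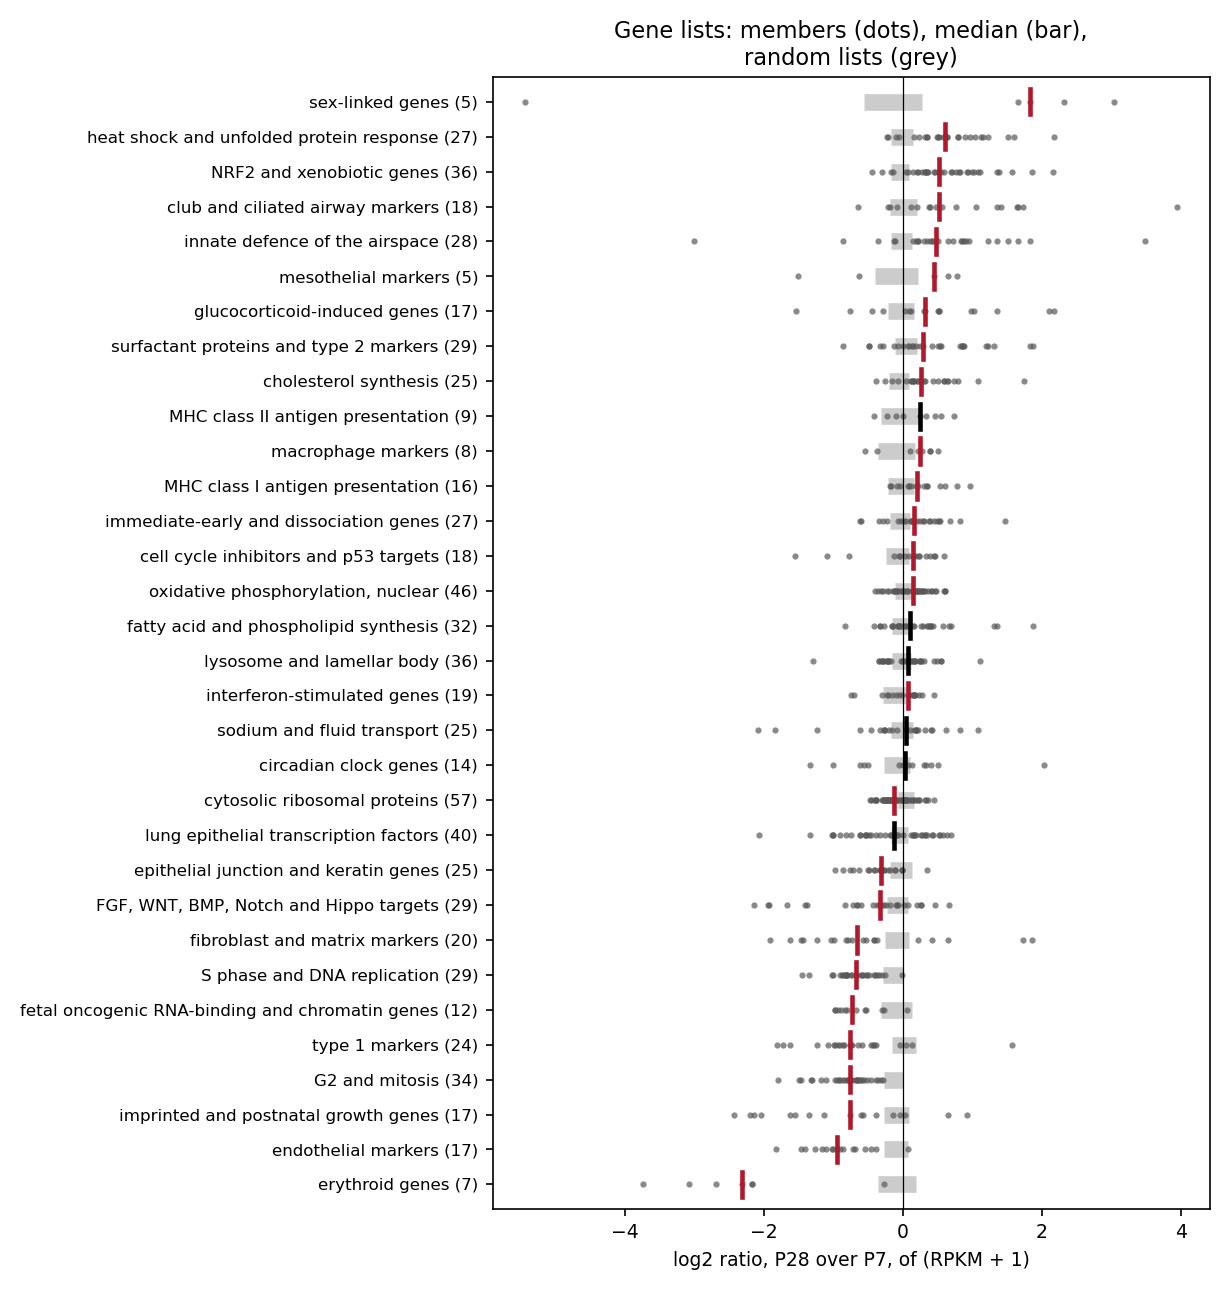
Rows are the gene lists with 5 or more measured genes (number in brackets), dots their genes' log2 ratios of P28 over P7, grey bars the central 95% of medians of 10000 random lists, and the vertical marks the list medians, red where outside the grey bar. Heat shock genes (0.61) and airway genes (0.52) lie to the right, and endothelial genes (-0.94) and erythroid genes (-2.31) to the left. The raw medians shift left when the libraries are rescaled to the same total, and those above 0 and up to 0.32 turn negative.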

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

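The settings that left out Rn45s, Lars2 and Malat1, removed a length and GC trend, or kept only genes with a counting interval excluding 1 were chosen after seeing the data. The counts of genes at least 2-fold higher and lower at P28 (114 and 189) moved to 226 and 530 with a pseudocount of 0.1, to 39 and 34 with a pseudocount of 5, and to 73 and 93 among genes of 5 RPKM or more, where fewer genes enter. Rescaling both libraries to the same total gave 65 and 445, and 67 and 420 without Rn45s, Lars2 and Malat1. The rescaling sets both totals to their mean. It lowers every P28 value by 1 factor and raises every P7 value by another, because the P28 total is larger. Under the other settings both counts stayed within 1.5 times, for example 142 and 155 with upper quartile rescaling, 116 and 185 with the median set to 0, 109 and 186 with the length and GC trend removed, and 111 and 185 with intervals excluding 1.

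The correlation of the libraries across genes (0.946) was 0.9211 with a pseudocount of 0.1, 0.9603 with a pseudocount of 5, 0.9776 with no filter on low values and 0.915 among genes of 5 RPKM or more. The share of the total RPKM in the 10 top genes was 26.458% at P7 and 42.322% at P28 with Rn45s left out.

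Of 406 list results recomputed, 378 were the same, 15 no longer stood apart, 13 newly stood apart and 0 reversed. The number of lists standing apart ranged from 18, among genes of 5 RPKM or more, to 28, and 19 lists stood apart in every setting that gave them a value. Those that newly stood apart under some settings were fatty acid and phospholipid synthesis, lysosome, MHC class II and epithelial transcription factors. With the stricter filter some lists had fewer than 5 genes and gave none. Of 1103 results for named genes 0 reversed a call. With a pseudocount of 5 some named genes lost their 2-fold call and others kept it. Those lost included Top2a (log2 ratio -0.91), Igf2 (-0.40), Cdh5 (-0.89), Shh (-0.79) and Idi1 (0.83). Rescaled to the same total, 10 of 41 named genes lost their call as higher, among them Sftpa1, Elovl1, Idi1 and Lpin2, as did Rnase4, Cyp2f2, Hp, Hspb1, Gstm1 and Cyp4b1 outside that set, while 0 of 43 lost their call as lower, 10 within 2-fold became lower, and 12 within 2-fold changed sign. No paired analysis was possible because the groups share only 1 replicate number, and no replicate could be left out with 1 library per age. Depth limits genes of a few reads, such as Ptprc with 8 reads and 1 read.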

Other observations

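The tests on opposite sex, on a single airway cell share, on fewer cells of every other type and on fewer endothelial cells were chosen after the results were seen. Some fibroblast and endothelial genes moved far. Postn, a matrix protein gene of fibroblasts and pericytes, had 4.03 RPKM at P7 and 0.346 at P28, Lox, the collagen cross-linking enzyme gene, 3.84 and 0.758, and Aplnr, the apelin receptor gene of endothelial cells, 3.52 and 0.274. The opposite held for Pdgfra, at 0.152 and 0.730 RPKM, and Dcn (decorin), at 0.490 and 1.35.

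The 303 genes at least 2-fold apart exceeded what read counting gives, since at most 3 genes were called in simulated pairs of unchanged expression. A trend with gene length and GC content also falls short as the whole cause, because 93.4% of the genes (283 of 303) kept their side after its removal. Linkage to the sex chromosomes accounts for few of them, as 3.0% of those with a position (9 of 300) lie on X or Y, against 3.09% of all measured genes. All 4 Y-linked genes tested had under 3 reads at P7 and over 30 at P28, with Xist the other way, which is what libraries from animals of opposite sex would give. Age, a sex difference in autosomal genes and variation between animals or preparations all stay open and untested.

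Most airway secretory genes were higher at P28 by unequal amounts. Whether one airway cell share that differs between the libraries accounts for this cannot be told apart from regulation, since 0 of 10 club genes had a counting interval wholly below 1, and 2 did with equal totals. A spread of 13.64 times between the bounds of Scgb3a1 and Aldh1a7 would need other cells to hold a baseline of these genes, which is not measured. A rise of ciliated cells as large as that of the median club gene is argued against. The median ratio was 1.272 over 8 ciliated genes, with a median upper bound of 1.57, against 2.65 over the club genes. Of the 8, 4 had intervals wholly above 1 (0 with equal totals) and 3 wholly below, so a smaller rise stays open. Whether ciliated cells were brought in together with club cells cannot be told, because the change in club cell share is itself not measured apart from regulation. A mix of airway cells from other levels of the airway, or secretory genes higher within type 2 or club cells at the later age, may apply and was not tested.

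Most endothelial and most fibroblast genes were lower at P28. Fewer cells of every other type, ciliated cells included, would have lowered ciliated and endothelial genes alike. However, the median lower bound of 8 ciliated genes (1.01) was 1.859 times the median upper bound of 23 endothelial genes (0.542). Rescaling leaves that ratio as it is. Ciliated genes mark airway epithelial cells, so the comparison does not test fewer non-epithelial cells of all types, which stays open. Fewer endothelial cells at P28 cannot be told apart from lower expression within them, because both lower the same genes: 21 of the 23 had intervals wholly below 1 and 0 wholly above, and a spread of 7.74 times between the bounds of Esam and Aplnr would need other cells to hold a baseline, which is not measured. The most abundant of them were Calcrl (12.4 and 5.68 RPKM), Esam (9.68 and 10.2) and Cdh5 (9.44 and 2.77). Of 23 fibroblast genes 17 had intervals wholly below 1 and 6 wholly above (4 with equal totals, 3 with 20 or more reads in each library, and with both 1, Mgp), so fewer fibroblasts, or fibroblasts of another kind or age, stay open.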
